A study of Homo sapiens with 12 samples.

How the data were processed

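Notch3 ChIP-seq was done on neural crest cells from the H9 line that carried a GFP or an N3ICD-GFP lentivirus, 6 days after transduction. Per the labels' protocols, cells were fixed in 1% formaldehyde, chromatin was digested enzymatically, and a Notch3 antibody was used in both groups. The series has 12 samples, with 3 ChIP and 3 input libraries per group. Peak lists of the 6 ChIP libraries were used, and the 6 input libraries were not analysed here. Per the submitters' processing notes, the tools were Bowtie2 2.2.1 (aligner), SAMtools 1.11, bedtools 2.30.0, deepTools 3.5.1 and MACS3 3.0.0a7 (peak caller), on build hg38. The options of these tools, and which control each peak call used, were not given in the sources used here. Enzymatic digestion cuts open chromatin more readily, and peaks called without a matched input can carry that preference.

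The authors called peaks in each library separately. The deposited fold of each peak is a ratio of ChIP pileup to local background at the summit, and it is used here only to describe and rank peaks within a library. The deposited −log10 p and −log10 q values come from the authors' peak caller. The lowest −log10 p was 3.3 in each library, so the deposited lists used a lenient p threshold, and most peaks have a weak q. The deposited signal is the summit pileup, a whole number of stacked fragments, given in the authors' table of the whole series. That table repeats the 6 lists: position, fold, p and q were equal for all 12583 peaks. Background pileup was computed as (pileup + 1) / fold − 1, and its lowest repeated value in a library was taken as the genome-wide background, which scales with depth times fragment length. Read totals were not given in the sources used here, so it is the only measure of depth, and it may have been scaled by the peak caller.

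Positions are 1-based on hg38. Peaks that overlapped by at least 1 bp were merged into 12268 regions. A region was N3ICD-only or GFP-only with peaks in at least 2 of the 3 libraries of that group and none of the other, and shared with at least 2 of each. Gene positions came from a RefSeq table of the same assembly, with 20037 protein-coding genes on chromosomes 1 to 22, X and Y. The table has no strand and no exons, so the planned distance to start sites was replaced by the distance to the nearer end of a gene, and exons, introns and UTRs are not stated. A region went to the gene with the nearest end within 100 kb. Near-identical gene copies make some assignments uncertain. No genome sequence was used here, so the planned motif results for RBPJ and other factors were not computed.

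Peak numbers, gene-end shares and overlap were compared between 3 and 3 libraries with two-sided exact permutation tests, whose smallest p is 0.1. Classes of regions were compared with Fisher's exact test. For each of 10 gene lists, the number of genes with an N3ICD-only region was set against 10000 random lists matched on deciles of the width of each gene's surroundings, one-sided, with Benjamini-Hochberg adjustment over the lists. All list genes were found in the gene table. The lists overlap: Notch targets share 5 genes with the pathway components, 3 with the mural markers, 1 with the smooth muscle genes, 1 with the extracellular matrix genes and 2 with the neural crest genes. Wilson intervals are at 95%. The number of N3ICD-only regions expected by chance came from 1000 random shifts of each library's peaks along each chromosome.

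The groups, tests, lists and most alternatives were fixed before the data were examined. Named genes follow a fixed rule. It takes the 15 N3ICD-only regions in all 3 N3ICD libraries with the highest mean percentile of fold, up to 10 genes of each list with an N3ICD-only region, and the top 5 GFP-only and top 10 shared regions (only 2 exist). NOTCH3, NRARP and the HES and HEY genes are named whatever their values. Alternatives covered the overlap rule, the q threshold, equal numbers of peaks, the number of libraries required, the distance to gene ends, the assignment rule, chromosomes, leaving out libraries and the replicate letter as a block. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

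The procedure was tested on simulated data. For the N3ICD-only comparison, with peak lists of the real sizes, 159 of 160 planted regions present in at least 2 N3ICD lists were recovered, with 2 false N3ICD-only regions and 1 false GFP-only region. The other simulated peaks were placed evenly along the chromosomes, whereas real peaks gather at some sites. The false counts therefore do not carry over to the real lists. For the gene lists over 20037 genes, 1.4% of 500 random lists of 25 genes had a p under 0.05, and all lists with 4 planted genes did.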

Results

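Chromatin bound by Notch3 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in neural crest cells made from H9, an established human embryonic stem cell line. Notch3 is a receptor whose intracellular domain (N3ICD) is released after ligand binding, enters the nucleus and acts on genes with the DNA-binding protein RBPJ and Mastermind coactivators. The cells had received a lentivirus for N3ICD with GFP, or one for GFP alone, 6 days earlier. The labels call the N3ICD cells mural, the cell class of pericytes and vascular smooth muscle, and the GFP cells neural crest. Each group had 3 Notch3 ChIP libraries, named A, B and C, and the series text states 3 independent differentiations. The 6 input libraries were not analysed here. The values are the authors' peaks, called separately in each library on hg38, and the fold at a peak is the authors' ratio of ChIP pileup to background. Total read numbers were not given in the sources used here. As a relative measure of depth, the genome-wide background implied by the deposited values was 1.46, 1.21 and 1.90 stacked fragments in GFP A, B and C, and 1.27, 1.58 and 0.926 in N3ICD A, B and C. The group means of this background were 1.52 ± 0.350 and 1.26 ± 0.329 (SD, n = 3 each), a difference within the spread between libraries (two-sided exact permutation p = 0.5).

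The first comparison asked whether the Notch3 antibody captured more sites in cells that carried N3ICD. Every N3ICD library had more peaks than every GFP library. There were 2226, 2490 and 3397 peaks in N3ICD A, B and C, and 1219, 1533 and 1718 in GFP A, B and C. The means were 2704 ± 614 and 1490 ± 252 peaks (SD, n = 3 each), a ratio of 1.81, with an exact permutation p of 0.1 (two-sided), the smallest that 3 libraries against 3 can give. The strongest peaks also stood higher with N3ICD. The highest fold was 15.4, 11.3 and 25.8 in N3ICD A, B and C, against 6.95, 6.99 and 6.09 in GFP A, B and C. The median fold of all peaks was alike, at 3.58 ± 0.0539 with N3ICD and 3.57 ± 0.102 with GFP (SD, n = 3 each; exact permutation p = 0.8). Most peaks of both groups were weak. A −log10 q of at least 1.3 was reached by 146, 352 and 678 peaks in N3ICD A, B and C and by 26, 28 and 139 peaks in GFP A, B and C (exact permutation p = 0.1). A −log10 q of at least 5 was reached by 13, 11 and 42 peaks and by 0, 2 and 5 peaks, in the same order.

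**Figure D1:**
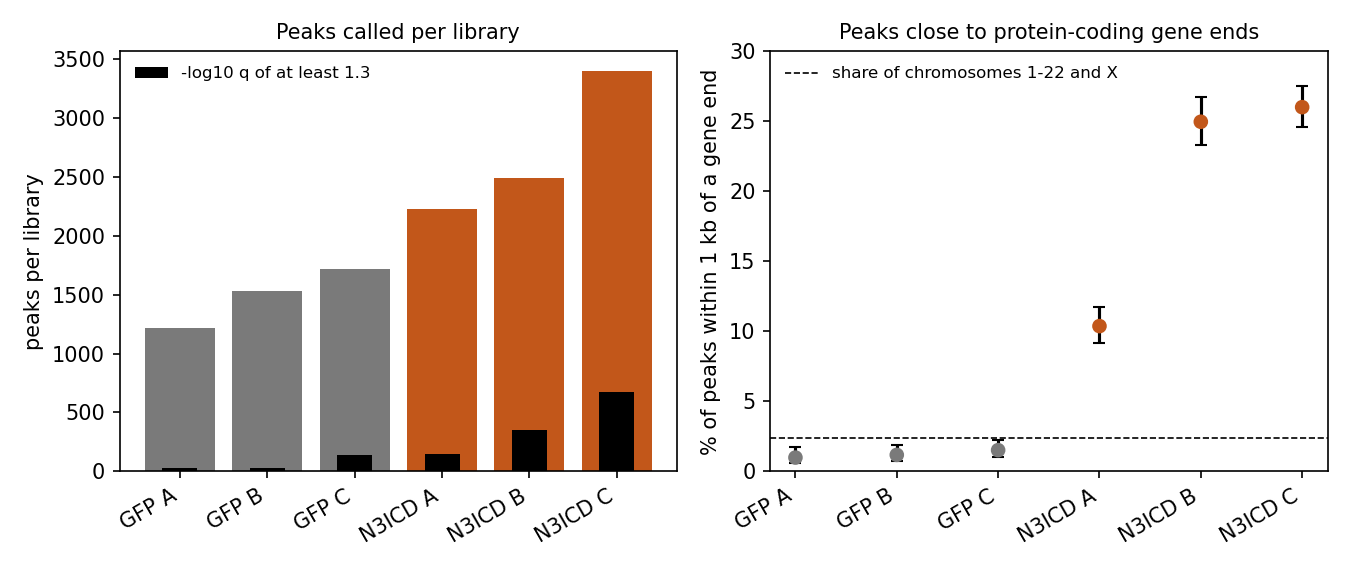
The left panel plots the number of peaks in each of the 6 Notch3 ChIP libraries, with the narrow black bars giving the peaks at a −log10 q of at least 1.3; the right panel plots the percentage of each library's peaks with a summit within 1 kb of a protein-coding gene end, with Wilson 95% intervals and the share of chromosomes 1 to 22 and X that lies this close as a dashed line. All 3 N3ICD libraries (2226 to 3397 peaks; 10.4% to 26% at gene ends) lie above all 3 GFP libraries (1219 to 1718 peaks; 0.984% to 1.51%).

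The next comparison asked which sites were found again and in which group. Overlapping peaks of the 6 libraries formed 12268 regions. An N3ICD-only region had a peak in at least 2 N3ICD libraries and in no GFP library, and there were 200 of these. The mirror class, GFP-only regions, held 28, and only 2 regions were shared by at least 2 libraries of each group. Of the 200 N3ICD-only regions, 24 were found in all 3 N3ICD libraries, 106 in B and C alone, 42 in A and C alone and 28 in A and B alone. Peaks moved along their chromosomes at random gave a mean of 4.36 N3ICD-only and 6.45 GFP-only regions in 1000 draws, with at most 12 of either (permutation p = 0.000999 for the N3ICD-only count, the smallest these draws can give). With an N3ICD library left out, a region needed a peak in both of the others, so the N3ICD-only count fell by construction. It was 129 without A, 65 without B and 52 without C. Among peaks at a −log10 q of at least 1.3 the N3ICD-only count was 40, and it was 6 at a −log10 q of at least 5. It was 95 when each library gave its 1219 most significant peaks, against 20 GFP-only regions.

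The 24 N3ICD-only regions found in all 3 N3ICD libraries were ranked among themselves by the mean percentile of fold. The top 5 of these 24 lay at genes of varied function, among them a vessel wall gene and NOTCH3 itself. The first was inside SULT4A1, a sulfotransferase family gene of the brain (chromosome 22, 43834208 to 43835236), with folds of 15.4, 11.3 and 18 in N3ICD A, B and C. The second of the 24 lay 148 bp from the end of MIDN, whose product midnolin brings nuclear proteins to the proteasome (chromosome 19, 1258883 to 1259545), with folds of 6.42, 7.01 and 25.8. The third of the 24 lay 3464 bp from MCAM, the adhesion molecule CD146 of pericytes and endothelial cells (chromosome 11, 119320454 to 119321725), with folds of 6.48, 5.81 and 8.12. The fourth of the 24, inside EXD3 (chromosome 9, 137315846 to 137316478; folds 6.19, 5.48 and 8.45), lay 13914 bp from NRARP, a feedback inhibitor of Notch signalling. GUCY1B1, which encodes a subunit of the nitric oxide receptor guanylate cyclase, had a region inside the gene (chromosome 4, 155759571 to 155760349; folds 4.68, 4.93 and 12.5). The other regions named by the rule were at SH3KBP1, LMLN, PHF21B, FOXK2, REEP3, FNIP1, VTI1A, DENND2B and CCDC97, with folds between 3.07 and 13.5. Of these, LMLN (chromosome 3, 198030784 to 198031310) had folds of 6.41, 4.65 and 13.5, and CCDC97 (chromosome 19, 41323615 to 41324508) had 11, 3.07 and 12.9. At a −log10 q of at least 5 in at least 2 N3ICD libraries, the regions left were those at SULT4A1, MIDN, EXD3, LMLN and CCDC97 and one 110454 bp from ADGRD1, an adhesion receptor gene named after its values were seen.

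**Figure D2:**
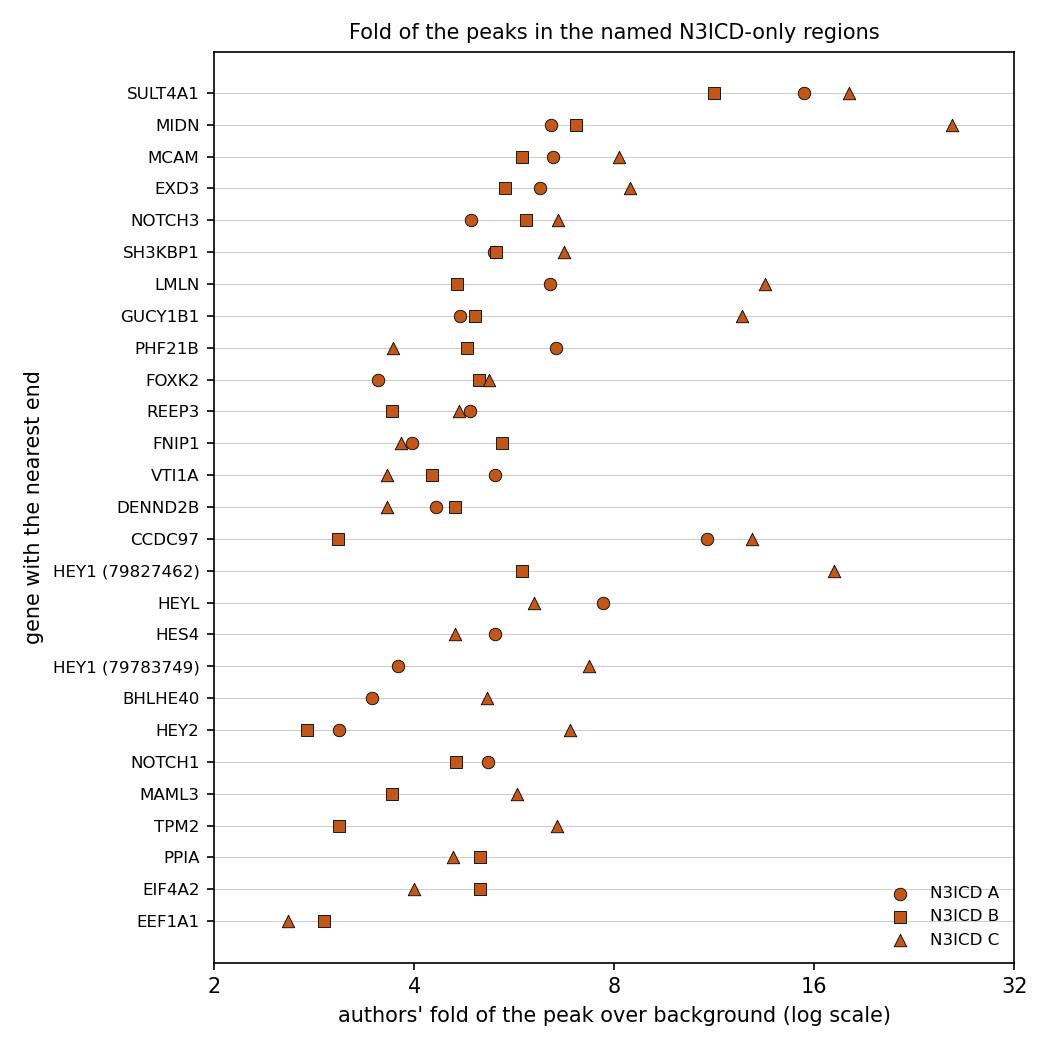
Each row is one of the N3ICD-only regions named by the rule, labelled by the gene with the nearest end (HEY1 has 2 regions, told apart by their start), and the horizontal log axis gives the authors' fold of the peak over background, with one marker per N3ICD library that had a peak; no GFP library had a peak in any row. SULT4A1 has the highest fold in N3ICD A and B (15.4 and 11.3), and MIDN in N3ICD C (25.8).

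GFP-only regions lay mostly outside genes. Of the 28, 7 were on the mitochondrial genome, none lay within 1 kb of a gene end and 4 lay within 100 kb of one. The top 5 by rank were on chromosome 9 (43210934 to 43211555), chromosome 2 (198984140 to 198984528), the mitochondrial genome (16016 to 16499), inside TSNARE1 on chromosome 8 (142222754 to 142223650) and on chromosome 20 (29507224 to 29507529), with folds of 3.47 to 5.87. The mitochondrial region of these was found in all 3 GFP libraries, with folds of 3.47, 4.96 and 4.15 in A, B and C. Both shared regions were weak. One lay 70017 bp from CENPC, a centromere protein gene (chromosome 4, 67398653 to 67399121; folds 2.73 to 3.46), and the other on chromosome 1 (124940240 to 124940734; folds 1.60 to 2.10) had no gene end within 100 kb. The GFP-only count was 12, 14 and 4 without GFP A, B and C, and 4 after leaving out the mitochondrial genome and regions farther than 100 kb from a gene end, which left 191 N3ICD-only regions.

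**Figure D3:**
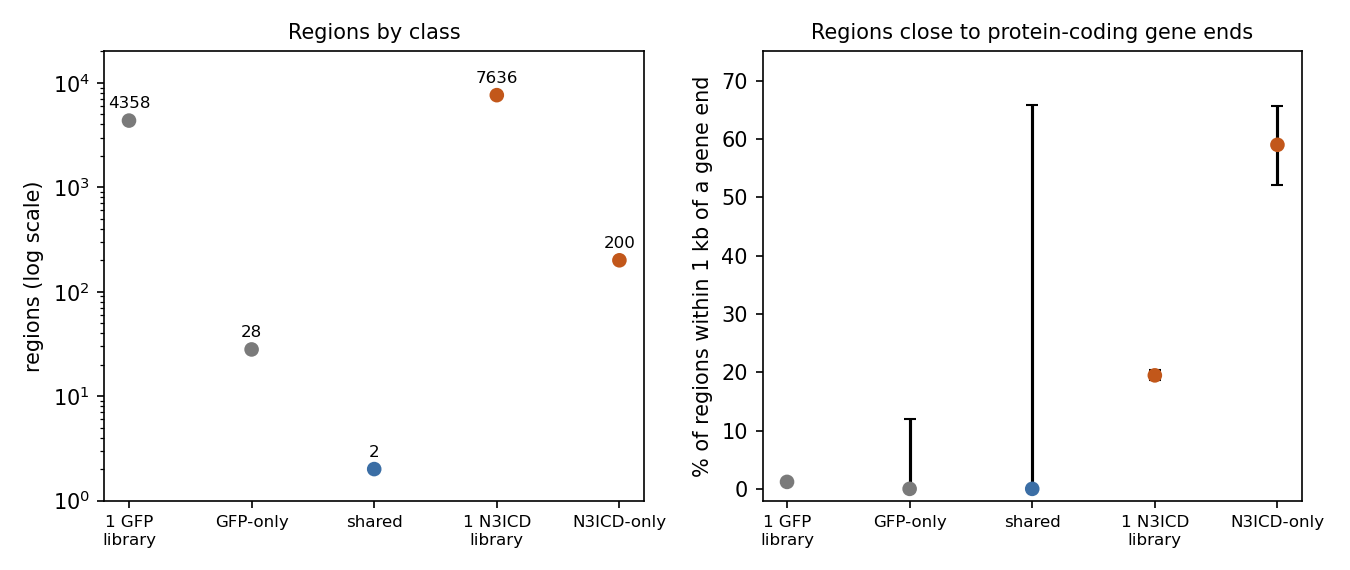
The left panel plots the number of regions (log axis) found in a single GFP library, in at least 2 GFP libraries only, in at least 2 libraries of each group, in a single N3ICD library and in at least 2 N3ICD libraries only; the right panel plots the percentage of each class with a summit within 1 kb of a protein-coding gene end, with Wilson 95% intervals. N3ICD-only regions stand highest in the right panel, at 59% of 200, against 1.19% of 4358 single-library GFP regions.

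Because N3ICD is part of the NOTCH3 protein, the NOTCH3 gene (chromosome 19, 15159038 to 15200995) was examined in each library. All 3 N3ICD libraries had a peak in a region inside the gene (15195578 to 15195951), with folds of 4.88, 5.88 and 6.58 in A, B and C. No GFP library had a peak inside NOTCH3. The N3ICD summits lay 5162, 5202 and 5213 bp from the high-coordinate end of the gene, the end at which its transcription starts. A second peak, in N3ICD A alone (15161493 to 15161716; fold 3.70), lay 2533 bp from the low-coordinate end, where the intracellular domain is encoded and where copies of a delivered coding sequence would align. Exon positions were not used here. This check of the labels counts peaks and carries no test.

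**Figure D4:**
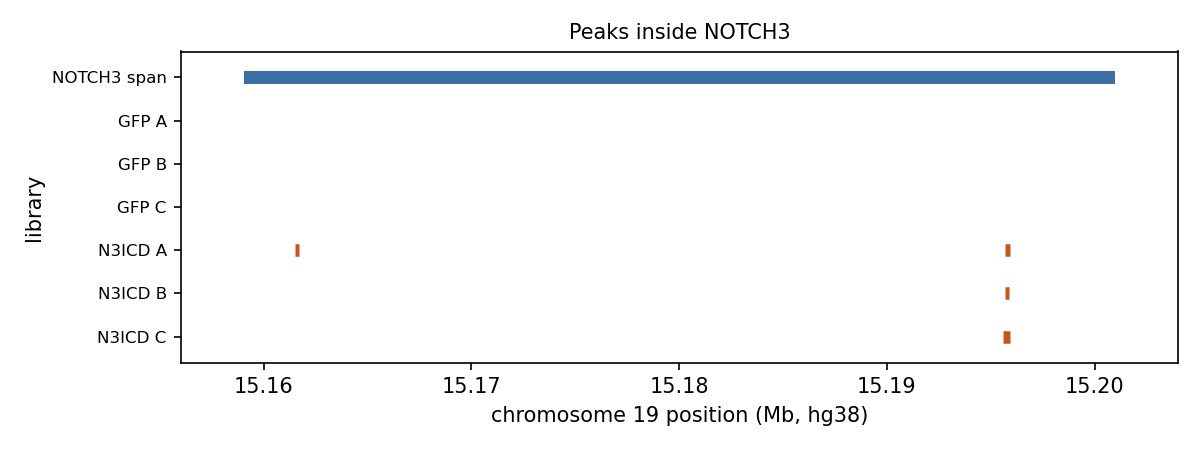
The horizontal axis is the position on chromosome 19 in Mb (hg38), the blue bar is the NOTCH3 gene span and each orange bar is a peak in the library of its row. The peak near 15.2 Mb appears in N3ICD A, B and C and in no GFP library, and the peak near the low-coordinate end in N3ICD A alone.

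Genes of the HES and HEY families, which encode the repressors best known as Notch targets, were then examined with NOTCH3 and NRARP whatever their values. No GFP library had a peak within 50 kb of any of these 12 genes, whereas N3ICD A, B and C had 10, 8 and 20 peaks there (mean 12.7 ± 6.43, SD, n = 3; exact permutation p = 0.1, the smallest possible). HEY1 had 2 N3ICD-only regions on chromosome 8, one 59843 bp away (79827462 to 79827921; folds 5.81 in B and 17.1 in C) and one 16375 bp away (79783749 to 79784226; 3.78 in A and 7.32 in C). HEYL held one inside the gene (chromosome 1, 39632857 to 39633551; 7.70 in A and 6.05 in C). HES4 had one 43 bp from its end (chromosome 1, 999789 to 1000501; 5.30 in A and 4.61 in C), and HEY2 one 99 bp from its end (chromosome 6, 125749282 to 125749830; 3.09, 2.75 and 6.87 in A, B and C). Some of these peaks were weak. The −log10 q at HEY2 was 0.104, 0.244 and 5.35 in N3ICD A, B and C. At the nearer HEY1 region it was 0.517 in A and 7.48 in C. NRARP had 2, 3 and 5 peaks within 50 kb in N3ICD A, B and C. HES1 had 1 such peak in N3ICD A and 3 in N3ICD C but no N3ICD-only region. HES6 had 1 in N3ICD C, HES7 had 2 in N3ICD B, and HES2, HES3 and HES5 had none in any library.

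The gene lists fixed before the data were examined asked which functions lay beside N3ICD-only regions, each region being assigned to the gene with the nearest end within 100 kb, 188 genes in all. Notch target genes led, with 6 of 25 (BHLHE40, HES4, HEY1, HEY2, HEYL and NOTCH3), where random lists of as many genes held 0.267 on average (adjusted permutation p = 0.001, from a p of 0.0001, the smallest that 10000 lists can give). BHLHE40, a transcriptional repressor of the circadian and hypoxia responses, had its region 1757 bp away (chromosome 3, 4986723 to 4987256; folds 3.46 in A and 5.15 in C). Of the Notch pathway components 3 of 31 had a region, NOTCH3, NOTCH1 (chromosome 9, 136588004 to 136588621, 42061 bp away) and the coactivator MAML3 (chromosome 4, 140154191 to 140154495), against 0.297 in random lists (adjusted permutation p = 0.00875). Of the pericyte and mural cell markers 3 of 33 had one, MCAM, HEYL and NOTCH3, against 0.298 (adjusted permutation p = 0.00875), but HEYL and NOTCH3 are also on the Notch target list. Of the smooth muscle contractile genes 1 of 20 had one, TPM2, a tropomyosin (chromosome 9, 35690699 to 35691507; folds 3.08 in B and 6.55 in C; adjusted permutation p = 0.372). None of the 32 extracellular matrix, 30 neural crest, 20 Schwann cell and neuron, 15 endothelial or 15 pluripotency genes had one (each adjusted permutation p = 1). The housekeeping control list also stood above random lists, with 3 of 24 genes against 0.160 (PPIA, EIF4A2 and EEF1A1, which encode a prolyl isomerase and 2 translation factors; adjusted permutation p = 0.0015). All 3 of its regions were within 1 kb of a gene end and found in N3ICD B and C alone, so the list held 0 without B or without C. The Notch target count was 3 without N3ICD A (adjusted permutation p = 0.0045) and 2 without C (adjusted permutation p = 0.008), and the pathway count was 1 without N3ICD B (adjusted permutation p = 0.341). By the rule that takes every gene within 50 kb of a region, the mural marker list, again with 3 genes, was no longer above random lists (adjusted permutation p = 0.103), nor was the housekeeping list (adjusted permutation p = 0.0977). At a −log10 q of at least 5, a setting added for the lists after the data were seen, none of the genes of any list had a region (each adjusted permutation p = 1). Some peaks in the N3ICD-only regions of list genes were weak. The −log10 q was 0.558 at BHLHE40 in N3ICD A and 0.945 at MAML3 in N3ICD B. It was 0.470 at TPM2 in N3ICD B and 0.147 at EEF1A1 in N3ICD C. GFP-only and shared regions were assigned to no gene of any list, but only 4 of 28 and 1 of 2 lay within 100 kb of a gene end. With so few to assign, this is no control for the lists.

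**Figure D5:**
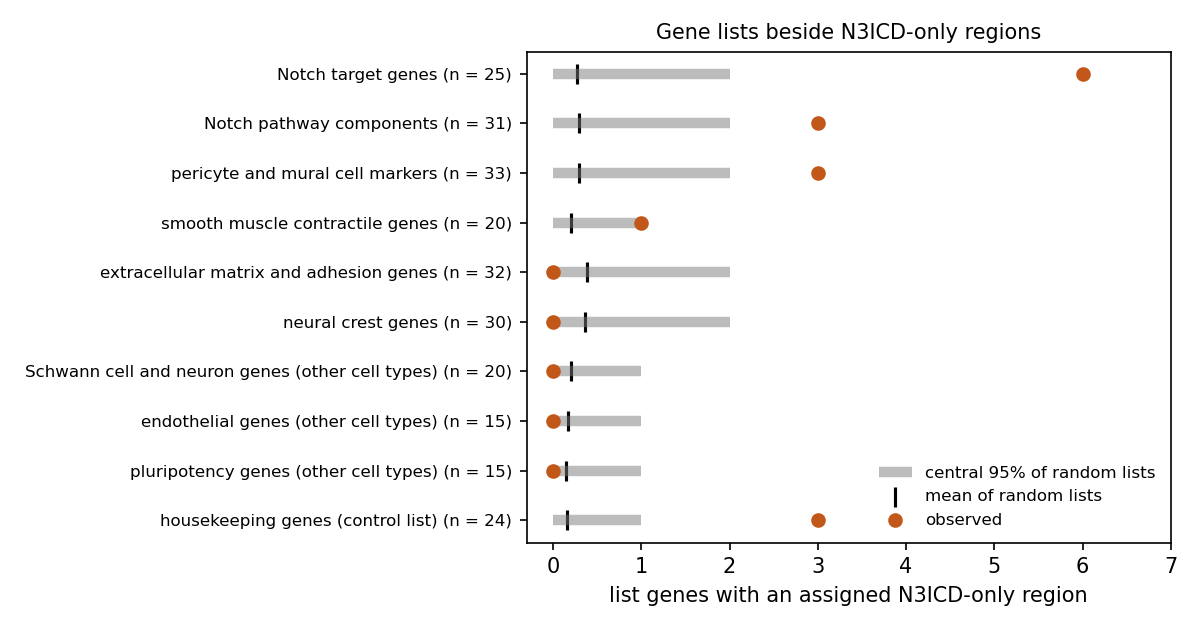
For each of the 10 gene lists, with its number of genes, the orange point is the number of list genes with an assigned N3ICD-only region, the black tick the mean of 10000 random lists matched on the width of the genes' surroundings and the grey bar their central 95%. The Notch target list reaches 6 genes and the Notch pathway, mural marker and housekeeping lists 3 each, all beyond the grey bars.

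Counted per library, Notch target genes with any assigned peak numbered 9, 9 and 13 in N3ICD A, B and C and 0 in each GFP library (exact permutation p = 0.1, adjusted p = 0.2). The mural markers numbered 7, 9 and 10 against 1, 1 and 1, and the neural crest genes 4, 7 and 8 against 1, 5 and 0. The Schwann cell and neuron genes numbered 2, 1 and 2 against 2, 2 and 1 (exact permutation p = 1). The housekeeping genes numbered 1, 5 and 5 against 0, 1 and 0 (exact permutation p = 0.2). Over all 20037 protein-coding genes, 1220, 1826 and 2295 had an assigned peak in N3ICD A, B and C, against 484, 676 and 654 in GFP A, B and C. No list passed the correction, which 3 libraries against 3 do not allow.

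The next comparison asked whether peaks lay close to promoters. Strand was not used here, so either end of a protein-coding gene stood in for the start site. In N3ICD A, B and C 10.4% (95% Wilson interval 9.18% to 11.7%), 25% (23.3% to 26.7%) and 26% (24.6% to 27.5%) of peaks had a summit within 1 kb of a gene end. In GFP A, B and C these shares were 0.984% (0.564% to 1.71%), 1.17% (0.744% to 1.85%) and 1.51% (1.03% to 2.21%), below the 2.40% of chromosomes 1 to 22 and X that lies this close. The means were 20.5% ± 8.75 and 1.22% ± 0.268 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). N3ICD-only regions were at gene ends more often still, 118 of 200 or 59% (52.1% to 65.6%), and 120 of them lay inside a gene. Of the regions found in a single library, 19.5% of 7636 with N3ICD and 1.19% of 4358 with GFP were at gene ends (Fisher's exact p = 1.40e-33 and 1.03e-135 against N3ICD-only regions, 2.33e-33 and 2.57e-135 after Benjamini-Hochberg adjustment over 5 comparisons of classes, of which only that with shared regions was planned). The planned comparison with shared regions had only 2 of these, neither at a gene end (Fisher's exact p = 0.172). Regions are not independent replicates, and the intervals cover counting error only.

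Finally, the overlap of whole peak sets was compared between libraries by the Jaccard index, the bases covered by both sets over the bases covered by either. Pairs of N3ICD libraries shared most, with a mean of 1.24% (0.968% to 1.70%) and 56 to 133 regions per pair. Pairs of GFP libraries shared 0.395% (0.170% to 0.662%) and 5 to 18 regions. Pairs of one library from each group shared 0.140% (0.0507% to 0.291%) and 2 to 18 regions. GFP C with N3ICD B (0.291%) and N3ICD A (0.205%), and GFP B with N3ICD B (0.181%), exceeded the pair of GFP A and B (0.170%), so the groups did not part in every pair. Overlap within groups exceeded that between groups by 0.676 percentage points (exact permutation p = 0.1 over the 10 splits of the 6 libraries, the smallest possible). Even the closest pair, N3ICD B and C, had few of its peaks in common.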

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

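The settings of −log10 q of at least 1.3, of leaving out mitochondrial and distant regions and of gene span first, and the lists at a −log10 q of at least 1.3 and 5, were chosen after seeing the data. No result changed direction, and the differences in peak number, gene-end share and Jaccard index kept their sign under every setting that gave a value. Their p-values cannot pass 0.05, which says nothing of stability. The Notch target list stayed past the threshold under 15 of 16 settings, with 2 to 7 genes, and lost it at a −log10 q of at least 5, where it and the pathway, mural marker and housekeeping lists held 0 genes (each adjusted permutation p = 1).

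N3ICD-only regions numbered 6 at a −log10 q of at least 5 (0 GFP-only, 0 shared), 40 at 1.3 (4 GFP-only), 95 with equal numbers of peaks (1 shared), 125 with reciprocal overlap of 50% (12 GFP-only) and 24 with support of all 3 libraries (1 GFP-only, 0 shared). Without mitochondrial and distant regions there were 191 N3ICD-only and 4 GFP-only regions. Stricter settings admit fewer peaks by construction. With one library or letter left out, N3ICD-only regions ranged from 52 to 201, GFP-only from 4 to 31 and shared from 0 to 2. The housekeeping list also lost its call at a −log10 q of at least 1.3 (1 gene, adjusted permutation p = 0.089), with equal numbers of peaks (1 gene), support of all 3 libraries (0) and every gene within 50 kb (3, adjusted permutation p = 0.0977). The mural markers lost it within 50 kb (3 genes, adjusted permutation p = 0.103), and the pathway components with support of all 3 libraries (1 gene, adjusted permutation p = 0.117). With one library or letter left out, the pathway list held 1 to 3 genes and the housekeeping list 0 to 3. The cause of these losses was not tested.

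Of 26 named genes with an N3ICD-only region, 24 kept one with summits within 200 bp, 22 with equal numbers of peaks, 19 with reciprocal overlap and 5 at a −log10 q of at least 5. Deviations from the group means gave r = 0.0168, 0.0385 and −0.141 for libraries of the same letter, over 274 regions. In the 200 N3ICD-only and 28 GFP-only regions of these the other group does not vary, which draws r towards no correlation. This check therefore cannot decide on pairing. The sources used here did not state whether a letter marks the same differentiation in both groups, so the letters are not taken as pairs in the main results. With them as a replicate block there were 201 N3ICD-only and 28 GFP-only regions, and peak numbers differed by 1214 (exact sign-flip p = 0.25, the smallest possible). Gene-end share at a −log10 q of at least 5 had no value, since GFP A had no such peak, and the motif alternatives were not run. With summit pileups of 7 to 10 fragments at the median peak, an unlisted site is not shown to be unbound.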

Other observations

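The tests of depth and of regions away from and at gene ends, and GUCY1A1, were chosen after the result was seen. Genes of a pair of subunits of the nitric oxide receptor guanylate cyclase, which relaxes vascular smooth muscle, had an N3ICD-only region each on chromosome 4: GUCY1B1 with folds of 4.68, 4.93 and 12.5 in N3ICD A, B and C, and GUCY1A1 (155667441 to 155668095) with 3.53 in A and 5.29 in C. The GUCY1A1 summit lay 819 bp from a gene end, and its −log10 q was 0.246 in N3ICD A and 2.98 in N3ICD C. The GUCY1B1 region (155759571 to 155760349) was the next of all regions on this chromosome. The 2 regions are therefore neighbours and not independent hits.

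N3ICD-only regions outnumbered GFP-only regions by 200 to 28, and of the 10 splits of the 6 libraries, too few for a share under 0.05, 1 gave a class as large, the real one, the highest other being 123. More peaks in the N3ICD libraries did not account for it alone, since equal numbers of peaks left a ratio of 4.75 (exact 95% interval 2.91 to 8.12). This interval treats regions as independent and leaves out the spread between libraries. Chance overlap spread over all gene ends did not account for the 200 N3ICD-only regions. Random gene ends gave a mean of 15.2 and at most 29. They were drawn from the ends of all protein-coding genes, so chance overlap among a smaller set of open promoters stays open. Mitochondrial DNA and repeats far from genes did not account for the 200 regions either. Leaving out the mitochondrial genome and regions over 100 kb from a gene end removed 4.50% of the N3ICD-only regions (191 left, against 4 GFP-only). Greater depth stays open, since the background pileup of the N3ICD libraries was 0.827 times that of the GFP libraries but the groups' values overlapped. N3ICD binding may be the source, as an untested hypothesis, but the labels also give the groups different cell classes, mural and neural crest, and this and chance differences between 3 and 3 cultures stay open too.

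Of the N3ICD-only regions 118 of 200 lay within 1 kb of a gene end. The share was 67.0% among the 100 regions with the lower mean percentile of fold and 51.0% among the other 100. The difference was 16 percentage points (Fisher's exact p = 0.0308). By another measure, the highest fold in any N3ICD library, the share was 30% among the top 20. This is consistent with weak capture of open promoters as the source of part of the gene-end regions. Of single-library GFP regions 1.19% lay there, so the same antibody gave no such share in the GFP cells. Those cells are labelled as another cell class and most of their peaks were weak. This comparison therefore cannot decide on antibody background at promoters in the N3ICD cells. Whether digestion or chromatin differed between the groups was not tested and stays open.

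Notch target genes and housekeeping genes both lay beside N3ICD-only regions more often than random lists. Among the 82 regions farther than 1 kb from a gene end, Notch targets were 4 (BHLHE40, HEY1, HEYL and NOTCH3). This was 39.6 times the mean of random lists (exact 95% interval 10.8 to 101, adjusted permutation p = 0.001). The interval treats genes as independent and leaves out the spread between libraries. Housekeeping genes were 0, which the distance cut fixes since all 3 lie within it. The fold was 31.5 without N3ICD A (2 genes, adjusted permutation p = 0.0075) and 26.2 without C, where the call ended with NOTCH3 alone among 30 regions (adjusted permutation p = 0.125), but peaks this far from gene ends put the list above random lists in N3ICD A, B and C each alone (4.81, 4.83 and 5.67 times, highest adjusted permutation p = 0.005). The distance cut itself took out regions at gene ends, so this test cannot decide whether capture at the ends of active genes is a source. It shows that Notch targets exceeded random lists matched on the width of the genes' surroundings, away from gene ends. This was not particular to them. Among these 82 regions, pathway components were 18.7 times their random mean (2 genes, adjusted permutation p = 0.015). Mural markers (HEYL, MCAM and NOTCH3) were 27.5 times theirs (adjusted permutation p = 0.002). No other list passed among these regions. Mural markers were also 3.90, 3.64 and 3.74 times in N3ICD A, B and C alone (highest adjusted permutation p = 0.005). Expression and open chromatin were not matched, and promoters inside genes or of genes not listed were not tested. HES4 and HEY2 lay within 1 kb of gene ends, where Notch targets were 12.2 times the mean of random lists (adjusted permutation p = 0.054). Housekeeping genes were 25 times the mean of their random lists there, so capture at the ends of active genes stays open for HES4 and HEY2. The motif test that would bear on RBPJ was not run.

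Chromosome X held 8.20%, 8.81% and 8.79% of the peaks in GFP A, B and C, and 6.83%, 3.33% and 3.18% in N3ICD A, B and C. A line of the log2 ratio of peak shares (N3ICD B and C over GFP) against genes per Mb was fitted to the autosomes. On it, chromosome X had a residual of −2.70 SD, chromosome 17 of 2.43 SD and chromosome 15 of 2.25 SD. Chromosome X and libraries B and C, which had the lowest shares, were picked from these same shares. The residuals are therefore descriptive only. The mitochondrial genome had 10, 1 and 9 peaks in GFP A, B and C and 1, 0 and 0 in N3ICD A, B and C.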
